A study of Mus musculus with 32 samples.

How the data were processed

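Liver poly(A) RNA of 32 outbred Crl:CD1(ICR) mice was sequenced with strand-specific libraries, per the labels. Mice were injected at 9 weeks of age with 2 subcutaneous doses of 25 mg/kg of a locked nucleic acid oligonucleotide (LNA), on consecutive days. Females received an LNA antisense to miR-802-5p (LNA-802) and males an LNA antisense to miR-1948-5p (LNA-1948). Control mice of each sex received a scrambled LNA. Livers were collected on day 3 or day 6. Each anti-miR group held 5 mice and each scrambled group 3 mice, which makes 8 groups. Groups were taken from the labels, and no mouse was left unassigned. LNA and sex go together in the design, and the day goes together with the series of libraries.

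The values came from 1 table of differential expression. Per the submitters' processing notes, reads were mapped with TopHat2 to the mm9 build, counted per RefSeq gene with featureCounts and compared with edgeR. The notes name no versions, and which edgeR test was run is not stated. The authors gave the mean FPKM of each group, per the file headers. They also gave an expression ratio for each of 7 comparisons, per the file headers. The ratio in the deposited table differed from the ratio of the mean FPKM by a near-constant factor per comparison, at most 0.093 on the log2 scale at the median. The authors gave an unadjusted and an adjusted p-value per gene and comparison, per the file headers. The adjusted p-value in the deposited table equalled a Benjamini-Hochberg adjustment over all of its genes, which was checked. The genes of 1 comparison stood in another order and were joined by their own gene symbols.

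The table holds neither counts nor values per mouse. The depth of each library and the spread between mice are therefore unknown, and no error stands beside a group mean. The planned fallback for such a table was used: changes were counted from the ratio and adjusted p that the authors computed with edgeR at a threshold of 0.05, with no test of each gene beyond theirs. The 4 anti-miR comparisons and the comparisons of scrambled males with scrambled females were read this way. Day 6 against day 3 within a treatment was described as a ratio of mean FPKM with a pseudocount of 1, at genes with at least 1 FPKM at either day, with no test. The day 6 to day 3 medians of lists used a pseudocount of 0.01, and 1 as an alternative chosen after the results were seen. Intervals of list medians are 95% bootstrap intervals over the genes of a list (10000 draws) and hold no spread between mice.

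Several computations were chosen after the content of the table was seen. The difference between 2 effects was tested per gene by an approximate two-sided z test. It took the standard error of each log2 ratio from its p-value and adjusted by Benjamini-Hochberg over genes with a group mean of at least 1 FPKM. The difference of a list between 2 comparisons was tested on these z values in the same way as single comparisons. Gene lists were tested with cameraPR of limma 3.58.1 in R 4.3.3, on z scores made from the authors' p-values and signs, over genes with at least 1 FPKM in either group. The preset correlation between genes was 0.01, with 0.05 and 0.2 as alternatives. An estimated correlation needs values per mouse, so the preset one was used, and genes that share a regulator can exceed it. Adjustment was over the lists tested in each comparison. Each list median was also placed among 10000 random lists matched on mean expression in 10 bins, whose smallest possible two-sided p is 0.0002.

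The 36 gene lists, 13 of them markers of cell types or tissues, were written before the data were examined. They hold 676 genes, of which 8 were absent from the table. Lists with fewer than 3 members at 1 FPKM or more were not tested. This applied to markers of T and NK cells, B cells, neutrophils, exocrine pancreas, and gallbladder and intestinal epithelium. The 3 immune cell lists among these had 0 members at 1 FPKM in any anti-miR comparison. In at least 1 anti-miR comparison it also applied to cell cycle genes and cholangiocyte markers. Neither passed the threshold in the anti-miR comparisons that could test it.

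The named genes follow a rule written before the data were examined. It takes the 10 largest rises and 10 largest falls past the threshold with at least 1 FPKM in the higher group, and 5 of each in the other contrasts. It adds up to 4 members of each list, smallest adjusted p first, that passed or are given as not passing, and 16 genes named always. List members given with a log2 ratio and no adjusted p did not pass the threshold in that comparison. Some genes that the rule names are not reported here. The list members that did not pass were not all taken in that order, so these, and names outside the rule, are to be read as chosen after their values were seen. Genes of the Cyp, Mup, H2-Q, Saa and Sult families have close copies whose reads the authors' counting could have divided between them, and their single values are uncertain.

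Sex-biased genes were taken from the scrambled mice of the other day (adjusted p that the authors computed with edgeR under 0.05 and at least 2-fold), so that no control library was shared. They were compared with the changed genes by a two-sided Fisher's exact test, adjusted over 16 tests. Seed matches were searched in the longest annotated 3' UTR of each gene as the 7-base site opposite positions 2 to 8 of the miRNA, read from the LNA sequence. These annotated UTRs come from another genome build and served only to list sites by gene symbol. Shuffled versions of each site, 100 per site, served as controls. Genes changed in 2 comparisons were counted only between comparisons with different mice.

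Both tests were tested on simulated data. With independent random z scores for the 9457 genes of the day 6 female comparison, 20 of 20 shifted lists were recovered and 0 of 600 other lists were called. Genes that share a regulator were not simulated, so false calls of coregulated lists were not measured. In the simulated day difference of LNA-802 over 9375 genes, 70 of 100 genes changed by 1 log2 unit and 95 of 100 changed by 2 were recovered, with 13 unchanged genes called. For LNA-1948 over 9119 genes, 76 of 100 and 98 of 100 were recovered, with 9 unchanged genes called. Genes were simulated as independent, with p-values exact for the standard errors used. The step that takes a standard error from an edgeR p-value was therefore not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used. The alternatives tried were other thresholds on fold and adjusted p, other FPKM minimums, other preset correlations, ranks, random lists, the ratio of mean FPKM, other definitions of sex-biased genes, and other seed sites.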

Results

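Liver RNA was compared between mice given an LNA against a microRNA and mice of the same sex given a scrambled LNA, 3 or 6 days after injection. LNA-802 has the sequence GAATCTTTGTTACTG, LNA-1948 the sequence GGCAGAATACTCATA and the scrambled control ACGTCTATACGCCCA. The 4 anti-miR groups held 5 mice each and the 4 scrambled groups 3 mice each. Group means in the authors' deposited table sum to between 198940 and 206757 FPKM, and between 9004 and 9327 genes reach 1 FPKM in a group. The table gives group means with no values per mouse and no errors, and library depth is unknown. All coordinates are mm9.

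In females at day 3, LNA-802 was followed by few single-gene changes. Cwc22, which encodes a splicing factor, and Ostm1, which encodes a lysosomal membrane protein, rose. Rufy4 and the basement membrane collagen gene Col4a3 fell at very low expression, and were chosen after their values were seen. Genes of cholesterol synthesis lay higher as a group, while interferon response genes and Kupffer cell markers lay lower. None of these lists passed at a preset correlation of 0.2.

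In the authors' deposited table, 4 genes changed in this comparison, 2 higher and 2 lower, at an edgeR adjusted p under 0.05. At an unadjusted edgeR p under 0.05 the authors' deposited table holds 636 genes. Among genes at 1 FPKM these are 385 of 9418, or 4.088%, which is no excess over what this threshold gives without any effect. The same share is 7.233% in LNA-802 females at day 6, and 3.835% and 4.913% in LNA-1948 males at day 3 and day 6. Cwc22 (chromosome 2, 77733709 to 77784413) has mean FPKM of 9.29 in scrambled and 19.9 in LNA-802 females in the authors' deposited table, a 2.10-fold rise (edgeR adjusted p = 0.0266). Ostm1 (chromosome 10, 42398721 to 42422268) rose 1.69-fold in the authors' deposited table, from 2.10 to 3.64 FPKM (edgeR adjusted p = 0.0151). Cux2, a transcription factor that represses male-biased genes in female liver, has a log2 ratio of -1.26 in the authors' deposited table and did not pass (edgeR adjusted p = 0.191).

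Among the fixed lists, 7 of 30 tested differed in females at day 3, and 1 of the 7 lay higher. Of 23 cholesterol synthesis genes, whose promoters bind SREBP2, 22 had a positive log2 ratio and 0 rose, also 0 when adjusted over the list alone. Mvd, Fdps, Dhcr7 and Mvk encode enzymes of the pathway and were chosen after their values were seen. They have log2 ratios of 0.73, 0.70, 0.63 and 0.61 in the authors' deposited table. The list gave a cameraPR adjusted p = 2.13e-09, and p = 0.0574 with the preset correlation at 0.2. Interferon response genes had 19 of 22 members with a negative ratio and 0 falls, or 1 adjusted over the list alone (cameraPR adjusted p = 2.8e-05, and p = 0.213 at a correlation of 0.2). Igtp, an interferon-induced GTPase chosen after its values were seen, has a log2 ratio of -1.70 in the authors' deposited table. Kupffer cell markers were negative in 13 of 13, with 0 falls adjusted over the list alone (cameraPR adjusted p = 0.000468, and p = 0.213 at a correlation of 0.2). The growth hormone and STAT5 genes were negative in 15 of 18 members with 0 falls, or 1 adjusted over the list alone (cameraPR adjusted p = 0.00279, and p = 0.496 at a correlation of 0.2). Mup genes, acute phase genes and hepatocyte markers also lay lower, with cameraPR adjusted p of 0.0197, 0.0404 and 0.0404, and p of 0.518, 0.778 and 0.661 at a correlation of 0.2. None of the 7 lists passed at that correlation.

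In females at day 6, genes of the ATF4 and unfolded protein response lay higher as a group with LNA-802. Hspa5 encodes the chaperone BiP, and Creld2 and Sdf2l1 encode proteins induced when unfolded protein accumulates. The metallothionein genes Mt1 and Mt2, which bind zinc and copper, fell, as did the acute phase genes Saa1 and Saa2. Cyp7a1, the rate-limiting enzyme of bile acid synthesis from cholesterol, also fell. Cyp2d9, a male-biased steroid hydroxylase, rose, and the female-biased Cyp2a4 fell.

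At day 6, 82 genes changed in LNA-802 females in the authors' deposited table, 44 higher and 38 lower, and 63 of these reached 1 FPKM (edgeR adjusted p under 0.05). Mt1 (chromosome 8, 96702988 to 96704227) fell 7.73-fold in the authors' deposited table, from 69.4 to 8.86 FPKM (edgeR adjusted p = 1.6e-29). Mt2 fell 7.39-fold in the authors' deposited table, from 36.5 to 4.86 FPKM (edgeR adjusted p = 3.71e-06). Saa1 and Saa2 fell 2.78-fold and 2.98-fold in the authors' deposited table (edgeR adjusted p = 1.99e-05 and 3.59e-05). Cyp7a1 (chromosome 4, 6192758 to 6202778) fell 2.61-fold in the authors' deposited table, from 34.7 to 13.2 FPKM (edgeR adjusted p = 0.00021). Pctp, a phosphatidylcholine transfer protein, fell 5.67-fold in the authors' deposited table (edgeR adjusted p = 0.000501). Psmc3ip, a recombination factor, fell from 1.25 to 0.0924 FPKM in the authors' deposited table (edgeR adjusted p = 2.19e-15), and its day 3 control mean is 0.0855 FPKM. The interferon-induced Ifit3, the sulfotransferase Sult2a6 and the MHC pseudogene H2-Ea-ps also fell, 2.66-fold, 2.62-fold and 14.2-fold in the authors' deposited table (edgeR adjusted p = 0.00417, 0.0482 and 0.032).

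Hspa5 (chromosome 2, 34627609 to 34632049) rose 1.77-fold in the authors' deposited table, from 136 to 238 FPKM in day 6 females (edgeR adjusted p = 0.003). Creld2 (chromosome 15, 88650075 to 88657111) rose 2.57-fold in the authors' deposited table, from 8.37 to 21.3 FPKM (edgeR adjusted p = 0.00047). Sdf2l1 rose 1.89-fold in the authors' deposited table (edgeR adjusted p = 0.0409). Of 16 ATF4 and unfolded protein response genes, 3 rose, or 6 adjusted over the list alone (cameraPR adjusted p = 4.77e-08). The list's transcription factor genes Atf4 and Atf5 have log2 ratios of 0.04 and -0.10 in the authors' deposited table, and were chosen after their values were seen. Syvn1, a ubiquitin ligase of ER-associated degradation, Manf, an ER stress-induced secreted factor, and Hyou1, an ER chaperone, were chosen after their values were seen. They rose 2.06-fold, 1.99-fold and 1.79-fold in the authors' deposited table (edgeR adjusted p = 7.13e-06, 0.00119 and 0.0284). Among the other rises, the peroxisome proliferator target Cyp4a14 went from 1.52 to 12.1 FPKM in the authors' deposited table (edgeR adjusted p = 0.031). Its control mean at day 3 is 18.7 FPKM in the authors' deposited table, so the day 6 control is the low value. Cyp2d9, Rassf4, Cks1b, Bmf and Car1 rose 2.87-fold, 2.97-fold, 2.46-fold, 2.34-fold and 2.32-fold in the authors' deposited table (edgeR adjusted p = 0.00803, 0.036, 0.0199, 0.0145 and 0.00047). These encode a steroid hydroxylase, a Ras-association protein, a cell cycle kinase subunit, a pro-apoptotic BH3 protein and a carbonic anhydrase. The linker histone gene Hist1h1c, the Golgi trafficking gene Arfgap3 and the epoxygenase gene Cyp2j9 rose 2.18-fold, 2.13-fold and 2.10-fold in the authors' deposited table (edgeR adjusted p = 0.00186, 1.14e-05 and 0.00813).

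The fixed lists of sex-biased genes lay in opposite directions in LNA-802 females at day 6, though 30 of 34 female-biased and 19 of 20 male-biased genes did not pass. Of 34 female-biased list genes, 3 fell and 1, Cyp4a14, rose, or 11 fell and 1 rose adjusted over the list alone, with 28 negative (cameraPR adjusted p = 4.95e-10). The female-biased Cyp2a4, Tox and Atp6v0d2 fell 1.98-fold, 1.92-fold and 1.73-fold in the authors' deposited table (edgeR adjusted p = 0.0218, 0.0286 and 0.0199). Of 20 male-biased list genes, 1 rose, or 7 rose and 1 fell adjusted over the list alone, with 18 positive (cameraPR adjusted p = 4.69e-07). Among 24 acute phase genes, 4 fell, or 6 adjusted over the list alone (cameraPR adjusted p = 5.1e-08, and cameraPR adjusted p = 0.152 on ranks). Kupffer cell markers were negative in 11 of 12 with 0 falls, or 2 adjusted over the list alone (cameraPR adjusted p = 3.26e-07). Lyz2, a lysozyme of macrophages, and Timd4, a receptor for dying cells, were chosen after their values were seen and have log2 ratios of -0.63 and -0.50 in the authors' deposited table. Interferon response genes were negative in 17 of 21 with 1 fall, also 1 adjusted over the list alone (cameraPR adjusted p = 0.00153, and p = 0.393 at a correlation of 0.2). Ribosomal protein genes were positive in 21 of 22, with 0 rises adjusted over the list alone (cameraPR adjusted p = 0.00529, and p = 0.0564 at a correlation of 0.05). Pericentral markers, urea cycle genes and cholesterol synthesis genes lay lower and clock genes higher, with cameraPR adjusted p of 0.023, 0.0251, 0.0399 and 0.0399, and p of 0.0826, 0.121, 0.159 and 0.121 at a correlation of 0.05. In total 11 of 31 lists differed, and 5 at a correlation of 0.2.

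In males at day 3, female-biased and xenobiotic metabolism genes lay higher as groups with LNA-1948. Hao2, a peroxisomal oxidase of hydroxy acids, is higher in female liver. The cytochrome P450 Cyp2c37 and the carboxylesterase Ces1g handle drugs and lipids. Serpina12, which encodes the secreted protease inhibitor vaspin, fell. Interferon response genes and Kupffer cell markers lay higher as groups.

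In males at day 3, the authors' deposited table holds 13 changed genes, 9 higher and 4 lower, and 11 reached 1 FPKM (edgeR adjusted p under 0.05). Hao2 (chromosome 3, 98678441 to 98697153) rose 3.87-fold in the authors' deposited table to 7.95 FPKM (edgeR adjusted p = 9.48e-05), and the scrambled females have 29.4 FPKM. The acyltransferase gene Acnat2, Ces1g and Cyp2c37 rose 2.25-fold, 2.34-fold and 1.79-fold in the authors' deposited table (edgeR adjusted p = 6.96e-05, 0.000693 and 0.000301). Ifi27l2a, an interferon-induced gene, and Mt2 rose 4.14-fold and 3.79-fold in the authors' deposited table (edgeR adjusted p = 0.00508 and 0.0239). Serpina12 (chromosome 12, 105266978 to 105282653) fell 2.49-fold in the authors' deposited table (edgeR adjusted p = 7.39e-08). The carboxylesterase Ces2b, the MHC class I gene H2-Q2 and Gpcpd1, an enzyme of glycerophosphocholine breakdown, fell 4.79-fold, 3.57-fold and 1.81-fold in the authors' deposited table (edgeR adjusted p = 0.013, 0.0397 and 0.00579). Socs2, an inhibitor of growth hormone signalling, has a log2 ratio of -1.20 in the authors' deposited table and did not pass (edgeR adjusted p = 0.118).

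Of 30 lists tested in males at day 3, 13 differed and 11 of these lay higher. The CAR/PXR xenobiotic genes were positive in 24 of 26, with 1 rise, or 7 adjusted over the list alone (cameraPR adjusted p = 3.5e-18). Cyp2c54, Cyp2c50 and Cyp3a11, chosen after their values were seen, have log2 ratios of 0.68, 0.44 and 0.35 in the authors' deposited table. Interferon response genes were positive in 19 of 19 with 0 rises, or 2 adjusted over the list alone (cameraPR adjusted p = 8.36e-17). Ifi44, Irf7 and Oasl2, all induced by interferon, were chosen after their values were seen and have log2 ratios of 2.13, 1.38 and 1.09 in the authors' deposited table. Kupffer cell markers were positive in 10 of 11 with 0 rises, or 9 adjusted over the list alone (cameraPR adjusted p = 8.36e-17). The complement gene C1qc, the complement receptor Vsig4 and the lectin Clec4f, chosen after their values were seen, have log2 ratios of 0.65, 0.58 and 0.44 in the authors' deposited table. Female-biased genes were positive in 17 of 20 with 2 rises, or 8 rises and 1 fall adjusted over the list alone (cameraPR adjusted p = 5.69e-12). Male-biased genes were negative in 23 of 27 with 0 falls, or 7 adjusted over the list alone (cameraPR adjusted p = 1.09e-11). NRF2 oxidative stress genes were positive in 18 of 19 with 1 rise, also 1 adjusted over the list alone (cameraPR adjusted p = 2.72e-10). Mup genes were negative in 16 of 17 with 0 falls, or 2 adjusted over the list alone (cameraPR adjusted p = 4.51e-06).

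Endothelial markers and matrix genes lay higher in these males, in 13 of 13 and 12 of 12 members, with 0 rises adjusted over the list alone (cameraPR adjusted p = 2.22e-05 and 2.29e-05). Stellate cell markers were positive in 10 of 11 (cameraPR adjusted p = 0.00206, and p = 0.119 at a correlation of 0.2). Ribosomal protein genes, acute phase genes and p53 response genes lay higher, with cameraPR adjusted p of 0.0161, 0.0471 and 0.0471, and p of 0.0936, 0.154 and 0.13 at a correlation of 0.05. At a correlation of 0.2, 9 of the 13 lists passed.

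In males at day 6, Mup genes, which encode pheromone carriers secreted into urine, lay higher as a group with LNA-1948, and listed female-biased genes lay lower. Cyp7b1, a male-biased oxysterol hydroxylase, rose. Hao2 fell, the reverse of day 3, together with the female-biased Cyp3a41a, Cyp2c40 and Cyp2b9. Genes of fatty acid oxidation and synthesis lay lower and heat shock genes higher.

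In the authors' deposited table, 30 genes changed in males at day 6, 10 higher and 20 lower, and 22 reached 1 FPKM (edgeR adjusted p under 0.05). Mup9 (chromosome 4, 60430918 to 60434824) rose 22.2-fold to 80.3 FPKM in the authors' deposited table (edgeR adjusted p = 0.00021), and its day 3 control mean is 27.4 FPKM. Mup17 and Mup16 rose 6.81-fold and 5.12-fold in the authors' deposited table (edgeR adjusted p = 0.00747 and 0.00566). Mup15 also rose in the authors' deposited table, from a control mean of 0.0663 FPKM (edgeR adjusted p = 0.0137), and its ratio rests on that value near 0. Cyp2a5 (chromosome 7, 27620357 to 27628283), a coumarin hydroxylase, rose 4.59-fold in the authors' deposited table (edgeR adjusted p = 0.00021), against a 1.88-fold fall in LNA-802 females of the same day (edgeR adjusted p = 0.00186). Cyp7b1 (chromosome 3, 17971949 to 18143338) and the amino acid decarboxylase Ddc rose 2.14-fold and 1.59-fold in the authors' deposited table (edgeR adjusted p = 0.00839 and 0.000376). The predicted gene Gm7120 and Hopx, a homeodomain protein, rose 2.07-fold and 1.63-fold in the authors' deposited table (edgeR adjusted p = 0.0386 and 0.046).

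In males at day 6, Hao2 and Cyp2c40 fell 6.04-fold and 7.48-fold in the authors' deposited table (edgeR adjusted p = 0.0145 and 0.046). The Hao2 means of LNA-1948 males in the authors' deposited table are 7.95 FPKM at day 3 and 1.52 at day 6, and those of scrambled males 2.04 and 8.91, so the controls moved between the days as well. Cyp3a41a and Cyp2b9 fell 27.3-fold and 6.19-fold in the authors' deposited table, to 0.0420 and 0.537 FPKM (edgeR adjusted p = 0.0156 and 0.0203). Fam213b, a prostaglandin synthase, and Rassf4 fell 3.01-fold and 2.82-fold in the authors' deposited table (edgeR adjusted p = 0.00123 and 0.00021). Rassf4 rose in LNA-802 females of the same day. Ankrd55, the MAP kinase phosphatase Dusp1, the glycogen-targeting subunit Ppp1r3b and 1810011O10Rik fell 2.21-fold, 1.74-fold, 1.68-fold and 1.64-fold in the authors' deposited table (edgeR adjusted p = 0.000376, 0.00123, 5.1e-05 and 0.00839).

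Of 30 lists tested in males at day 6, 13 differed and 5 of these lay higher. The Mup genes had 4 rises among 16, or 10 adjusted over the list alone, and 14 positive (cameraPR adjusted p = 9.34e-19). Mup20 (chromosome 4, 61711268 to 61715151), the pheromone darcin, has 555 and 1534 FPKM in the authors' deposited table and did not pass, whereas Mup3, chosen after its values were seen, has 2785 and 2682 FPKM. Fatty acid oxidation genes were negative in 23 of 25 with 0 falls, or 3 adjusted over the list alone (cameraPR adjusted p = 1.6e-10). Cyp4a14, Cyp4a10 and Acot1, which oxidise or hydrolyse fatty acyl groups under PPARA, were chosen after their values were seen and have log2 ratios of -3.45, -2.70 and -0.89 in the authors' deposited table. Female-biased genes were negative in 12 of 17, with 4 falls, or 8 falls and 1 rise adjusted over the list alone (cameraPR adjusted p = 6.37e-09, and cameraPR adjusted p = 0.0534 on ranks). Male-biased genes were positive in 20 of 27 with 1 rise, or 5 adjusted over the list alone (cameraPR adjusted p = 8.71e-08, and p = 0.0525 at a correlation of 0.2). Heat shock genes were positive in 14 of 14 with 0 rises, or 2 adjusted over the list alone (cameraPR adjusted p = 3.79e-08). The chaperone genes Hsph1, Hsp90aa1 and Hspa8, chosen after their values were seen, have log2 ratios of 0.67, 0.52 and 0.34 in the authors' deposited table. Fatty acid synthesis genes were negative in 18 of 20 with 0 falls, or 1 adjusted over the list alone (cameraPR adjusted p = 1.35e-07). The desaturase Scd1 and the elongase Elovl5, chosen after their values were seen, have log2 ratios of -0.94 and -0.55 in the authors' deposited table.

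ATF4 and unfolded protein response genes were positive in 13 of 15 members in males at day 6 (cameraPR adjusted p = 0.000689, and p = 0.165 at a correlation of 0.2). Hepatocyte markers were negative in 13 of 15 (cameraPR adjusted p = 0.00218, and p = 0.222 at a correlation of 0.2). Stellate cell markers, acute phase genes, gluconeogenesis and glycolysis genes and Kupffer cell markers lay lower, and clock genes higher. Their cameraPR adjusted p are 0.025, 0.0391, 0.0449, 0.0466 and 0.0391, and p at a correlation of 0.05 are 0.0734, 0.143, 0.143, 0.127 and 0.12. By the ratio of mean FPKM the gluconeogenesis and glycolysis median changes sign, from -0.05 to 0.01. At a correlation of 0.2, 5 of the 13 lists passed. In none of the 4 anti-miR comparisons did cameraPR pass hepatocyte transcription factors, bile acid genes, oxidative phosphorylation genes, periportal markers, erythroid markers, cell cycle genes or cholangiocyte markers where tested. Exocrine pancreas markers had 1 member at 1 FPKM and gallbladder and intestinal markers 2, so these were not tested.

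**Figure D1:**
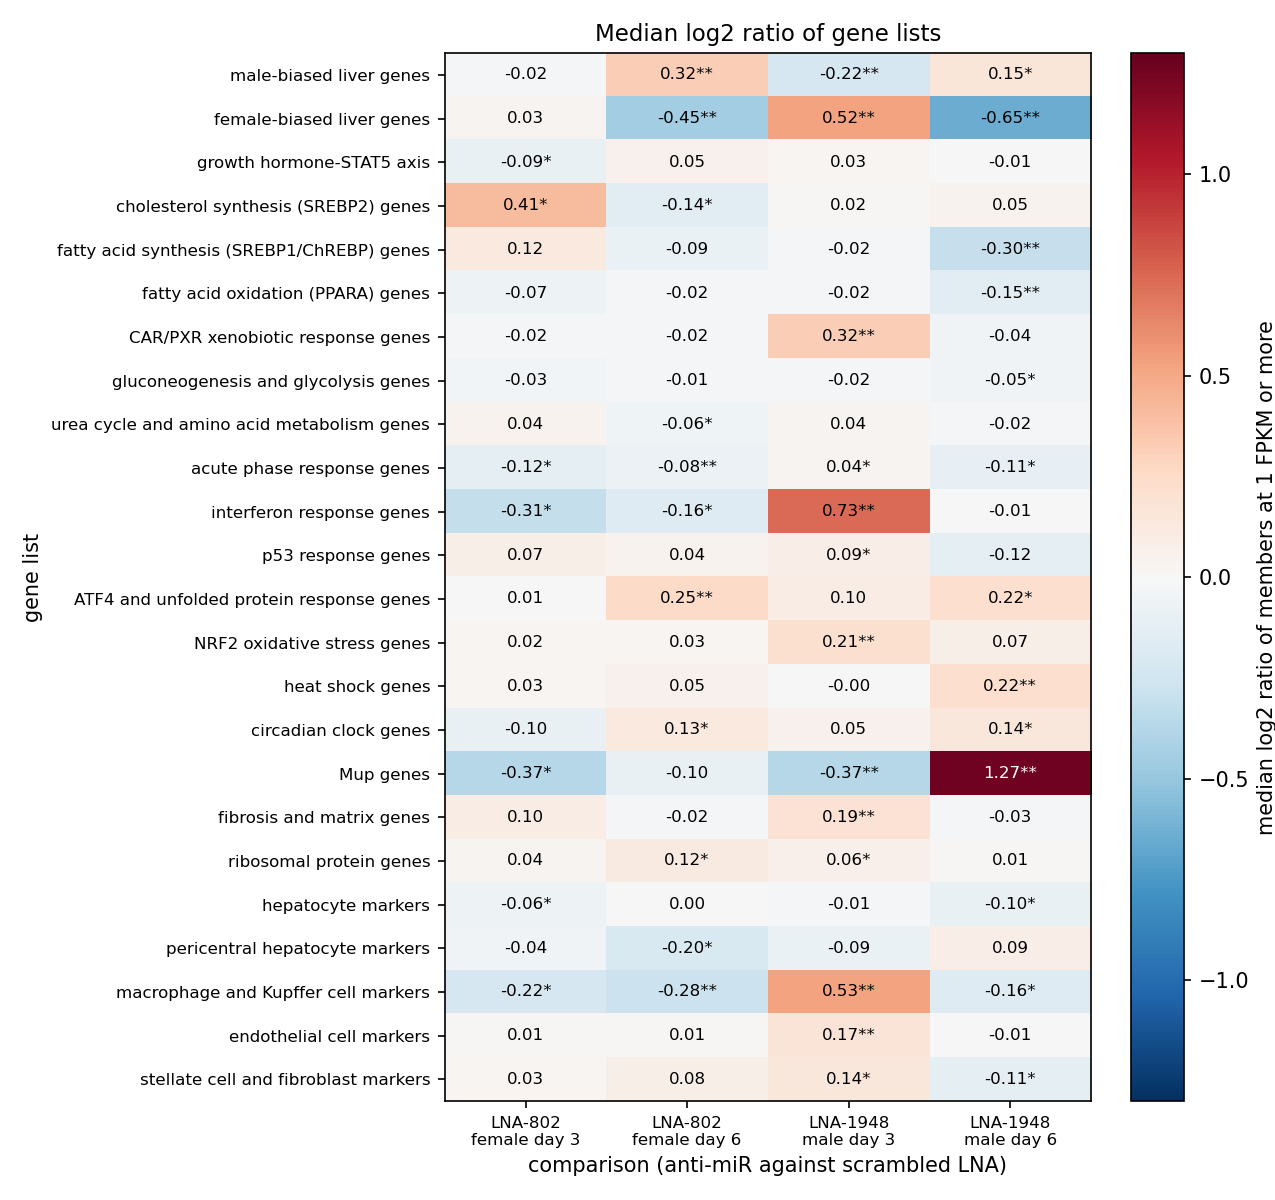
Median log2 ratio (anti-miR over scrambled) of each fixed list (y axis) in each comparison (x axis). One star marks a list past an adjusted p of 0.05 with cameraPR at a preset correlation of 0.01, and a second star the same at 0.2.

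At the lowest preset correlation, the fixed lists of sex-biased genes differed between days with each LNA, and between LNAs at day 3. At day 6 only the female-biased list differed between LNAs, and not at a higher preset correlation. Cholesterol synthesis genes differed between days with LNA-802 only, and fatty acid synthesis and oxidation genes with LNA-1948 only. Between LNAs, no cholesterol or fatty acid list passed at the highest preset correlation. In LNA-1948 males, Hao2, Cyp3a41a, Cyp2b9 and Cyp2c40 had positive log2 ratios at day 3 and fell at day 6. Interferon response genes and Kupffer cell markers, higher with LNA-1948 at day 3, were lower with LNA-802.

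The test of the day difference passed 7 of 9375 genes for LNA-802 and 46 of 9119 for LNA-1948, by approximate z tests with Benjamini-Hochberg adjustment. Between the LNAs, 24 of 9356 genes differed at day 3 and 46 of 9354 at day 6 by the same test. Each count of 46 holds a pair of genes with identical values, which may be 1 measurement under both names. The pairs are H2-Q6 with H2-Q8 between the days, and H2-Q7 with H2-Q9 between the LNAs. The 5 largest differences of each sign are named. At day 3, Mup15, the interferon-induced GTPases Tgtp2 and Tgtp1, Gm12250 and the retinoic acid hydroxylase Cyp26b1 had lower log2 effects of LNA-802 than of LNA-1948, by differences of -10.95, -5.16, -4.94, -3.92 and -3.71. The male-biased Selenbp2, Zbtb7c, the enamel protein gene Tuft1, Nop58 and Nolc1 had higher effects of LNA-802, by 3.30, 2.88, 1.98, 1.25 and 0.96. At day 6, Cyp4a14, Gdpd3, Rassf4, Cyp2c40 and Cyp4a10 had higher effects of LNA-802, by 6.47, 5.29, 3.07, 3.05 and 3.03. Psmc3ip, Sult2a1, Mup9, Mt2 and Cyp2a5 had lower effects, by -6.75, -6.65, -5.03, -3.45 and -3.11 (approximate z test adjusted p = 5.37e-05, 0.00843, 5.37e-05, 0.000885 and 6.76e-09). At least the differences of Mup15, Sult2a1 and Psmc3ip rest on group means near 0. By lists, interferon response genes and Kupffer cell markers were lower with LNA-802 than with LNA-1948 at day 3 (cameraPR adjusted p = 1.26e-19 and 6.53e-14). Female-biased and CAR/PXR genes were lower too (cameraPR adjusted p = 4.32e-16 and 1.14e-08), and cholesterol synthesis genes higher (cameraPR adjusted p = 0.00203, and p = 0.37 at a correlation of 0.2). At day 6, Mup genes were lower with LNA-802 (cameraPR adjusted p = 1.68e-11), and fatty acid oxidation genes higher (cameraPR adjusted p = 4.17e-05, and p = 0.366 at a correlation of 0.2). LNA and sex cannot be separated in these differences.

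Few genes changed in 2 comparisons in the authors' deposited table. For LNA-802, Ostm1 changed the same way at both days and Rufy4 the opposite way. For LNA-1948, only Hao2 changed at both days, and in opposite directions. Between LNAs, 0 genes changed at day 3 in both, and Rassf4 and Cyp2a5 changed in opposite directions at day 6. At an unadjusted edgeR p under 0.05 and 1 FPKM, 48 genes moved the same way and 18 the opposite way between days for LNA-802, against 13 and 46 for LNA-1948. Between the LNAs, 13 genes moved the same way and 40 the opposite way at day 3. At day 6, 58 moved the same way and 38 the opposite way. This order depends on the threshold. At an unadjusted edgeR p under 0.01, 10 moved the same way and 10 the opposite way at day 6, against 2 and 9 at day 3. Under 0.05 at day 6, genes higher in both and lower in both number 39 and 19, against 9.11 and 8.21 expected. The opposite pairs number 21 and 17, against 9.62 and 7.78 expected, so every pair exceeds its expected count. Spearman correlations across genes of the log2 ratios of the 2 days were 0.164 for LNA-802 and -0.119 for LNA-1948. Between the LNAs they were -0.121 at day 3 and 0.132 at day 6, where Pearson correlations were -0.177 and 0.009. Genes are not independent in these counts and correlations.

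The scrambled mice show how male and female liver differ. Y-linked genes such as Eif2s3y, Kdm5d and Uty, and the male-biased Cyp4a12a, Cyp2d9, Elovl3 and Mup20, were higher in males. The sulfotransferases Sult2a1 and Sult3a1 were higher in females, as was the X-inactivation transcript Xist.

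In the authors' deposited table, 812 genes differed between scrambled males and females at day 3 (331 higher in males, 481 lower) and 1073 at day 6 (463 and 610), at an edgeR adjusted p under 0.05. Cyp4a12a has 0.192 FPKM in females and 131 FPKM in males at day 3 in the authors' deposited table (edgeR adjusted p = 2.04e-251). Cyp2d9 and Mup20 have 10.1 and 8.97 FPKM in females, against 304 and 1174 in males, in the authors' deposited table (edgeR adjusted p = 4.7e-93 and 5.59e-80). Sult2a2 is listed at 0 in males against 33.4 in females, in the authors' deposited table. Of 27 male-biased list genes, 22 were higher and 1 lower in males at day 3, and of 34 female-biased list genes 28 were lower and 2 higher (cameraPR adjusted p = 2.31e-108 and 2.48e-211). At day 6 the counts are 23 and 1 of 26, and 32 and 2 of 36 (cameraPR adjusted p = 1.82e-87 and 4.63e-157). The fixed lists thus split the control mice by sex. Kupffer cell markers lay lower in males, with 8 of 13 falling at day 3 and 9 of 12 at day 6 (cameraPR adjusted p = 9.8e-06 and 3.74e-06). Interferon response genes lay lower in males too (cameraPR adjusted p = 0.000522 and 0.00022, and p = 0.202 and 0.133 at a correlation of 0.2). In scrambled females, 38 genes differ at least 2-fold between the days by ratio of mean FPKM, and 32 in scrambled males, with no test.

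**Figure D2:**
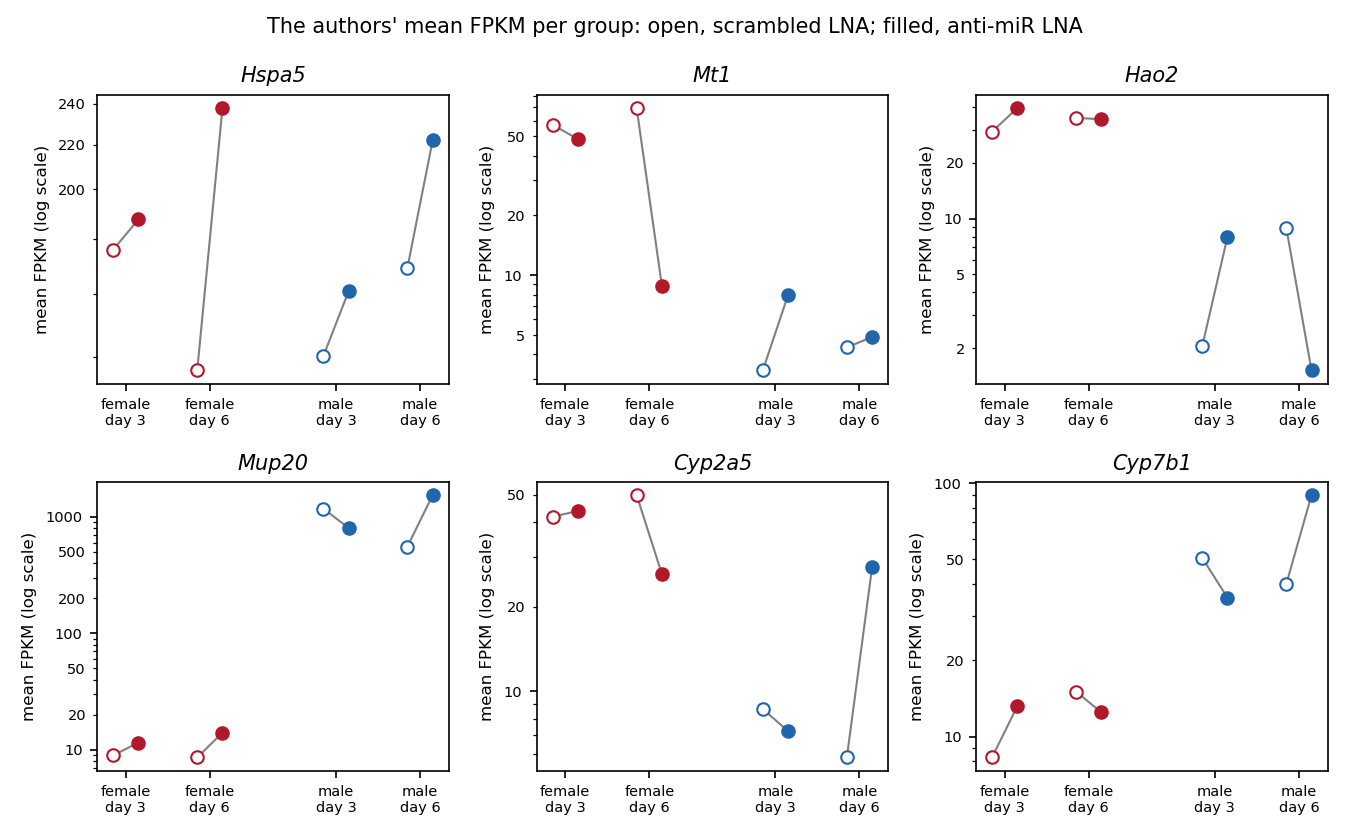
Mean FPKM (y axis, log scale) of Hspa5, Mt1, Hao2, Mup20, Cyp2a5 and Cyp7b1 in the 8 groups (x axis) of the authors' deposited table, with open points for scrambled LNA and filled points for anti-miR LNA. The means carry no error bars because the table used here holds group means alone.

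Sex-biased genes were also defined from the scrambled mice of the other day, and counted among the genes that each LNA changed. In LNA-802 females at day 6, the female-biased genes that changed fell. In LNA-1948 males, the female-biased genes that changed rose at day 3, and at day 6 more of them fell than rose. The male-biased genes that changed went the other way at each day, though the day 6 pattern depends on how sex bias is defined.

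Of 161 female-biased genes in LNA-802 females at day 6, 11 fell, 0 rose and 140 had a negative log2 ratio (Fisher's exact adjusted p = 1.44e-12). Of 82 male-biased genes, 1 rose and 61 had a positive ratio (Fisher's exact adjusted p = 0.645). In LNA-1948 males at day 3, 5 of 132 female-biased genes rose and 93 were positive (Fisher's exact adjusted p = 8.96e-08), and 2 of 141 male-biased genes fell and 101 were negative (Fisher's exact adjusted p = 0.00432). At day 6, 5 of 94 female-biased genes fell and 1 rose, with 55 negative (Fisher's exact adjusted p = 6.45e-07 for falls). Of 122 male-biased genes at day 6, 3 rose and 86 were positive (Fisher's exact adjusted p = 0.00072). In LNA-802 females at day 3, 0 sex-biased genes changed, with 29 of 98 male-biased genes positive and 96 of 188 female-biased genes positive. These Fisher's tests treat coregulated genes as independent. By cameraPR at a correlation of 0.2, without adjustment, the female-biased sets passed with LNA-802 at day 6 (n = 161, p = 0.000772) and with LNA-1948 at day 3 (n = 132, p = 0.0135). The sets that did not pass there were male-biased genes with LNA-802 at day 6 (n = 82, cameraPR p = 0.0538), with LNA-1948 at day 3 (n = 141, p = 0.0789) and at day 6 (n = 122, p = 0.0589), and female-biased genes with LNA-1948 at day 6 (n = 94, p = 0.245). Neither did the LNA-802 day 3 sets, female-biased (n = 188, cameraPR p = 0.679) or male-biased (n = 98, cameraPR p = 0.355, against p = 0.003 at a correlation of 0.01). Of the 27 male-biased genes of the fixed list, 0 fell with LNA-1948 at day 3 (Fisher's exact adjusted p = 1). With sex bias taken from the same day, which shares control libraries with the effect, the LNA-1948 day 6 pattern is not seen in the signs. There 66 of 112 female-biased genes were positive, with 2 rises and 5 falls, and 77 of 145 male-biased genes were positive, with 2 rises and 2 falls. The counts of changed genes are small.

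**Figure D3:**
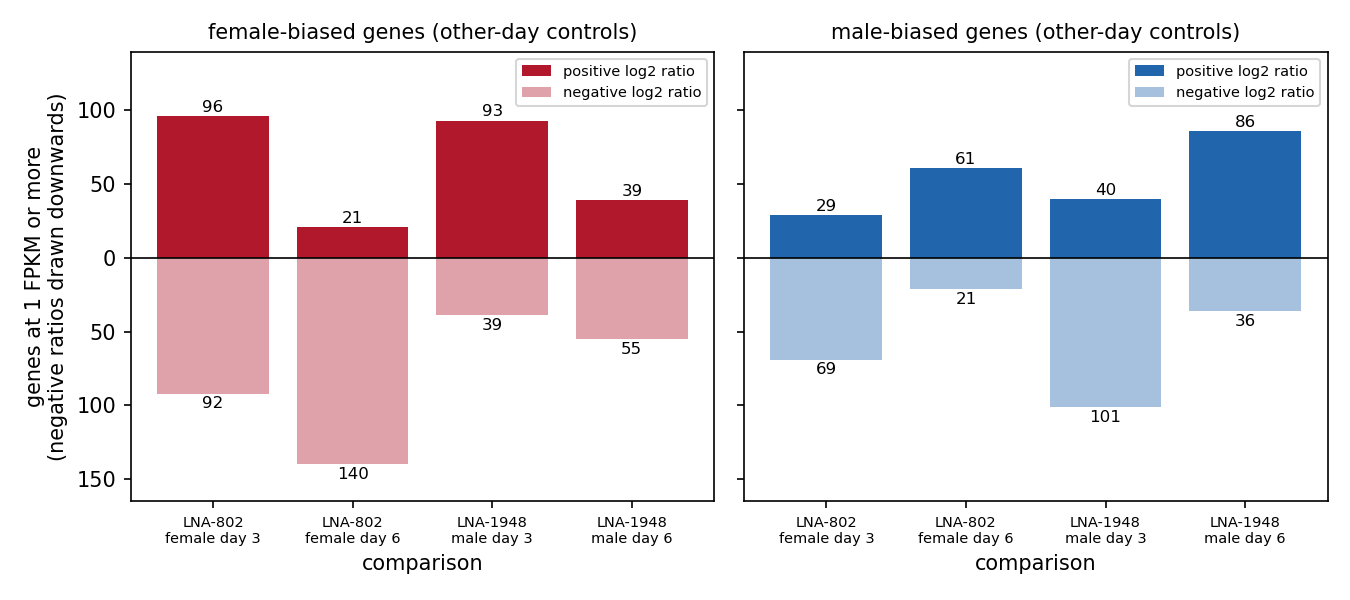
Number of female-biased and male-biased genes (y axis) with a positive or negative log2 ratio in each anti-miR comparison (x axis). Negative ratios are drawn downwards, and sex bias is taken from the scrambled mice of the other day.

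Genes with a site for the targeted microRNA in their 3' UTR did not stand apart. The site GTTACTG of miR-802 and the site ACTCATA of miR-1948 were searched. In each of the 4 comparisons the targeted microRNA's own site gave a cameraPR adjusted p of 0.735. The mean z of genes with the own site minus that of genes without it was negative in each comparison. It was -0.048 and -0.102 in LNA-802 females at day 3 and day 6, and -0.137 and -0.049 in LNA-1948 males. Of 100 shuffled sites, 9 and 67 gave an equal or more positive difference in these females, and 80 and 90 in these males. Among genes that rose with LNA-802 at day 6, 5 of 38 searched carry the longer 8-base site, which was counted after the result was seen. They are Nfxl1, Rassf4, Tmed9, Tmem248 and Tor1b (Fisher's exact p = 0.00781, unadjusted). The 7-base site is in 5 of 38 rises as well (Fisher's exact p = 0.61), or in 2 of 38 with the shortest UTR (Fisher's exact p = 0.699). All genes with the 8-base site did not stand apart either (cameraPR adjusted p = 0.747).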

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

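The tests of the difference between days, and the tests that weigh explanations, were chosen after the contents of the authors' deposited table or the results were seen. A gene or list is listed here where the test of the difference itself passed an adjusted p of 0.05 between day 6 and day 3 of the same LNA, and, for lists, also at a preset correlation of 0.05. Values are the day 6 minus the day 3 log2 ratio, and for lists the adjusted p.

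For LNA-802 in females, 7 genes differed between the days by the approximate z test. The metallothionein Mt1, the bile acid enzyme Cyp7a1 and the MHC pseudogene H2-Ea-ps were lower at day 6, by differences of -2.67, -2.03 and -7.25. H2-Ea-ps has log2 ratios of 3.42 at day 3 and -3.83 at day 6. Without values per mouse it is unknown whether single mice of this outbred stock carry them. The pro-apoptotic genes Bmf and Bik, the GTPase regulator Asap3 and Rassf4 were higher, by 2.89, 1.99, 1.23 and 3.28. By cameraPR, cholesterol synthesis genes (adjusted p = 7.3e-11) and female-biased genes (1.14e-06) were lower at day 6 than at day 3, and ATF4 and unfolded protein response genes (3.93e-06) and growth hormone and STAT5 genes (0.00139) higher. At a preset correlation of 0.2 only cholesterol synthesis passed among these 4, with p = 0.0254. The 2 further lists past the threshold did not hold at a correlation of 0.05.

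For LNA-1948 in males, 46 genes differed between the days, and only some of them are named here. The steroid and xenobiotic enzymes Cyp3a41a, Cyp2b9, Cyp2c40 and Cyp2c37 were lower at day 6 than at day 3, by -9.18, -3.85, -3.56 and -1.32. Hao2 and Fam213b were lower too, by -4.55 and -2.06. The pheromone carriers Mup9 and Mup13 were higher by 5.13 and 3.10, the hydroxylases Cyp2a5 and Cyp7b1 by 2.48 and 1.62, and the MHC genes H2-Q8, H2-Q6 and H2-Q2 by 3.16, 3.16 and 2.81. H2-Q8 and H2-Q6 have identical log2 ratios at both days, so they may be 1 measurement listed under both names. The MHC gene H2-K1, chosen after its values were seen, went the other way, by -1.27. Ces2b, Serpina12, Gpcpd1 and Ddc were higher by 2.83, 1.27, 1.09 and 0.88. The authors' counting could have divided reads between copies of the Cyp, Mup and H2-Q families, so single values are uncertain.

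By cameraPR, Mup genes (adjusted p = 1.35e-18), male-biased genes (2.87e-17) and heat shock genes (6.11e-05) were higher at day 6 than at day 3 in LNA-1948 males. Female-biased genes (9.01e-17), interferon response genes (1.34e-10), CAR/PXR genes (3.41e-10) and Kupffer cell markers (3.87e-11) were lower. Genes of fatty acid oxidation (5.32e-05) and synthesis (0.000172), matrix genes (0.000528), NRF2 genes (0.000779), acute phase genes (0.00559) and p53 genes (0.00648) were lower too. Markers of stellate (0.000128), endothelial (0.000612) and erythroid cells (0.0183) were also lower. At a correlation of 0.2, 6 of these 16 passed: Mup, male-biased, female-biased, CAR/PXR and interferon response genes, and Kupffer cell markers. The 4 further lists past the threshold did not hold at a correlation of 0.05.

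The ATF4 and unfolded protein response genes lay higher as a list in LNA-802 females at day 6, where 3 of 16 rose. A higher share of hepatocytes is argued against, since the hepatocyte marker median is 0.004 (bootstrap interval over its genes -0.045 to 0.044) against 0.249 for the list. A low level in the day 6 control mice stays open, since their median against day 3 is -0.212 (interval -0.320 to -0.051), while that of the LNA mice is 0.139 (0.035 to 0.208), and with a pseudocount of 1 they are -0.170 and 0.112. A response to any LNA would cancel only if the scrambled LNA gave it to the same degree, which was not tested. A response that both anti-miR LNAs share also stays open. The list lies higher in LNA-1948 males (cameraPR adjusted p = 0.000689, and p = 0.165 at a correlation of 0.2). It lies higher still with LNA-802 (cameraPR adjusted p of the difference = 0.00796, and p = 0.0561 at a correlation of 0.05). Inhibition of miR-802 is the biological explanation that the design names. It cannot be told apart from these, nor from other effects of the single LNA sequence used against miR-802. The level of mature miR-802 is not among the values used here. In the seed search, Hspa5, Creld2, Sdf2l1, Syvn1, Manf and Hyou1 each had 0 sites GTTACTG, so that search shows no direct targets among them.

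The female-biased genes of the fixed list lay higher at day 3 and lower at day 6 in LNA-1948 males, while the sets from the controls were near 0 at day 6, with medians of -0.073 by the other day and 0.117 by the same day. A female mouse in a male group is argued against, since the highest Xist mean of a male group is 0.0393 FPKM in the authors' deposited table, against 33.7 in the lowest female group. The control means alone do not account for the reversal, since the LNA-1948 means shifted too. The LNA-1948 median of day 6 against day 3 is -1.15 (interval -2.489 to -0.294), or -0.833 (-1.158 to -0.222) with a pseudocount of 1. The control median of 0.470 (-0.100 to 0.844), or 0.133 with that pseudocount, adds to the difference. These intervals resample genes and not mice, so they cannot decide whether variation between mice gave these shifts. Male-biased genes shifted the other way (cameraPR adjusted p = 2.87e-17), which a shift of all sex-dependent genes needs. Day goes together with the library series and the spread between mice is unknown, so the day, a series effect, variation of the mice of both groups and the inhibition of miR-1948 stay open.

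The Mup genes lay higher as a list in LNA-1948 males at day 6, where 4 of 16 rose. Reads moved between Mup copies are argued against for the family sum, since losses come to 7.53% of the gains in the authors' deposited table, or 25.8% without Mup20, which did not pass and gives 70.8% of the gains. The 4 changed members stay uncertain, since they gain only 179.6 FPKM of 1383. Male-biased genes other than Mup genes also lay higher as a list (n = 25 genes, unadjusted cameraPR p = 6.51e-08, and p = 0.0123 at a correlation of 0.2, where the whole male-biased list has an adjusted p = 0.0525). A low day 6 control stays open, since the authors' deposited table gives Mup20 at 1174 FPKM in day 3 controls, 555 in day 6 controls and 1534 with LNA-1948.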

How the results depend on the processing

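The other preset correlations, ranks, random lists, minimums of 0.1 FPKM, adjustment over expressed genes, the ratio of mean FPKM and a pseudocount of 1 for day medians of lists were chosen after the authors' deposited table was seen. Over 858 results and 1743 alternatives, 1574 kept their call or stayed within 1.5 times or the bootstrap interval. Of the rest, 84 lost a call, 35 gained one, 48 moved and 2 called list medians changed sign, and the cause was not tested. The 1574 include alternatives that could not change a call, such as a higher preset correlation for a list not called. A correlation of 0.2 alone removed 42 list calls, and one of 0.05 removed 20. Of the 183 list medians, 18 of lists not called also changed sign by the ratio of mean FPKM and count as moved. In females given LNA-802, the count of changed genes at day 3 went from 4 to 0 at an adjusted p of 0.01, and to 2 among genes at 1 FPKM, also 2 when adjusted over these. At day 6 it went from 82 to 42 at 2-fold and to 40 at an adjusted p of 0.01. In males given LNA-1948, 13 genes at day 3 became 8 at an adjusted p of 0.01 and 20 when adjusted over genes at 0.1 FPKM. At day 6, 30 became 16 at 0.01, 48 when adjusted over genes at 1 FPKM and 55 over genes at 0.1 FPKM. Between the sexes, 464 and 529 genes stood at 2-fold at day 3 and day 6. Differences at an adjusted p of 0.01 were 21 between days for LNA-1948, and 8 and 25 between LNAs at day 3 and day 6. A pseudocount of 0.1 gave 90 and 94 genes between days in scrambled females and males. With same-day controls, which share libraries with the effect, Fisher's exact adjusted p went to 2.01e-08 for male-biased genes higher with LNA-802 at day 6, and to 0.0344 and 0.0133 for male-biased genes lower and female-biased genes higher with LNA-1948 at day 6. With the fixed lists it went to 1 for male-biased genes lower at day 3 and 0.104 for male-biased genes higher at day 6 with LNA-1948. At 2-fold, 0 genes changed the same way at both days with LNA-802, and 1 changed the opposite way between LNAs at day 6. At a preset correlation of 0.05, cameraPR called 4, 6 and 8 lists for LNA-802 at day 3, day 6 and LNA-1948 at day 6. At 0.2 it called 0, 5 and 5 of these, and 6 and 5 between the sexes at day 3 and day 6. Random lists called 11 for LNA-802 at day 3, and ranks 7 for LNA-1948 at day 6. By the ratio of mean FPKM, the gluconeogenesis and glycolysis median in LNA-1948 males at day 6 became 0.008 from -0.047, and the cholangiocyte median between the sexes at day 6 became -0.082 from 0.016. No paired analysis was possible because the table used here holds group means alone. For the same reason DESeq2, limma voom, other normalizations, count filters, library sizes without the 20 most abundant genes, fewer groups in the fit, leave-one-out, the estimated correlation and fry were not run.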

Other observations

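The correlations across genes, the shared genes at unadjusted p and the tests below were chosen after the results were seen. In LNA-802 females, 14 of the 20 genes with an unadjusted edgeR p under 0.01 at both days moved alike and 6 in opposite directions. Those that follow moved alike, and did not pass the threshold at day 3. Rabac1, a regulator of vesicle traffic, has log2 ratios of 0.67 at day 3 and 0.82 at day 6 in the authors' deposited table. Tor1b, a chaperone of the ER and nuclear envelope, has 0.49 and 0.62, Tmem123 0.50 and 0.62, and Pctp -1.97 and -2.50 in the authors' deposited table. Tgtp2, an interferon-induced GTPase, has -3.07 and -1.45, and Atp6v1c1, a subunit of the vacuolar proton pump, has -0.52 and -0.53 in the authors' deposited table.

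In LNA-1948 males, 13 of the 15 genes with an unadjusted edgeR p under 0.01 at both days moved in opposite directions. The other 2 moved alike: Arrdc3, an arrestin-domain adaptor, has log2 ratios of -1.02 and -0.54 and Socs2 -1.20 and -0.65 in the authors' deposited table. The clock output gene Dbp, a transcription factor, has log2 ratios of 1.16 in LNA-802 females and 1.96 in LNA-1948 males at day 6 in the authors' deposited table.

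One hypothesis is that LNA-802 may raise the load on protein folding in the endoplasmic reticulum of female hepatocytes by day 6. The hepatocyte marker median of 0.004 argues against more hepatocytes, but the low control median of -0.212 leaves the control mice open. Repeating the day 6 comparison with more scrambled and uninjected females, and measuring spliced Xbp1 and BiP protein, would test it.

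Another hypothesis is that the sex-dependent genes could follow a pulse of growth hormone signalling that changes between day 3 and day 6 after LNA-1948. Male-biased genes shifted against the female-biased ones between the days (cameraPR adjusted p = 2.87e-17), as such a change would need. The growth hormone and STAT5 genes did not pass between the days (cameraPR adjusted p = 0.517) or at day 3 or day 6 (cameraPR adjusted p = 0.957 and 0.307). That cannot decide the question, since the list mixes activators and inhibitors of the pathway. Members moving in opposite directions would cancel in a test of signed values. Socs2 has a negative ratio at both days, so this 1 gene did not reverse. Day and library series cannot be told apart. Livers taken every day after injection, with plasma growth hormone and phosphorylated STAT5 in each mouse, would test it.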
